A study of Mus musculus with 9 samples.

How the data were processed

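RNA of spermatids from wild type, Wip1-/- and Wip1-/- Atm+/- mice was measured on 9 Illumina Mouse WG-6 arrays, 3 per genotype. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase treatment, and turned into biotinylated cRNA with the Ambion MessageAmp kit. Per the file headers, the deposited scanner table holds for each probe and array a signal intensity that is not normalized and a detection p-value. The scanner software and any background step before deposit are not given in the sources used here, and the lowest signals, between 54.7 and 65.1, lie well above 0. The authors' second table holds processed intensity values of the same arrays. Its columns share 1 distribution on a linear scale, with medians of 110.972 to 111.065, and each column ranks its probes as the scanner signal of the same array does (rank correlation of 1 on each array). By its values it was quantile normalized with no centring per gene and no background removed, a reading from the values that the headers do not state. In 895 cells the detection p-value had lost its decimal point and stood as a whole number and was read as thousandths. Read so, these cells differed by at most 0.00391 from the detection p-value that other cells of the same array gave at the same signal, and all were 0.125 or more, so none passed the detection threshold.

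The authors' table lists 45279 probes. Complete scanner values exist for 43582 of them, and the remaining 1697, of which 1593 have a gene name, were left out of the main comparisons because their scanner cells are blank in the table used here. The platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10376. By Entrez identifier 34807 probes matched the gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names, for the chromosome of a gene and for which genes neighbour each other. No coordinates are given, since no build is named in the files. All 9 arrays were assigned to genotypes from the genotype label, and 0 columns of sample values were left unused.

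Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which estimates background from the detection p-values, adds an offset of 16 and applies quantile normalization. The offset shrinks fold changes of dim probes, and quantile normalization removes any difference in the total amount of RNA between genotypes. Probes with a detection p under 0.05 on at least 3 of the 9 arrays were kept (18867 probes, 15494 with 1 gene). For each gene the probe with the highest mean over the 9 arrays was tested, which left 10556 genes, 3467 of them with several detected probes. A linear model with 1 mean per genotype was fitted to all 9 arrays with lmFit and eBayes of limma (6 residual and 5.09 prior degrees of freedom), and the 3 contrasts were tested two-sided with Benjamini-Hochberg adjustment at 0.05. Genes differing among the genotypes came from the moderated F test. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over all lists with at least 5 members tested and the 3 contrasts, and also with an estimated correlation and with fry, whose test asks whether the members of a list move one way and not whether they differ from other genes. In limma the 3 contrasts share arrays, so 100 simulations drew every array anew. For the changes against wild type all groups were drawn equal to wild type, and for moving back the group labelled Wip1-/- Atm+/- was drawn equal to Wip1-/- with the Wip1-/- shift kept. The share of the Wip1-/- shift held by the arrays labelled Wip1-/- Atm+/- was measured with 1 wild type and 1 Wip1-/- array held out from the choice of genes, in all 9 combinations.

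The gene lists covered p53 targets, DNA damage signalling and homologous recombination, DNA methylation and heterochromatin, the piRNA pathway, histone-to-protamine exchange, acrosome and round spermatid, elongating spermatid and flagellum, sex-chromosome genes of spermatids, imprinted genes, interferon response, immediate early and heat shock genes, apoptosis, the mitotic cell cycle, cytosolic ribosomal proteins, the mitochondrial respiratory chain, retroelement-derived probes, the X and Y chromosomes, and markers of spermatocytes, spermatogonia, Sertoli, Leydig, peritubular with vascular and stromal, macrophage and immune, erythroid and epididymal cells. The groups, tests, lists and the rule for naming genes were fixed before the data were examined. The rule named Ppm1d and Atm, the 10 largest rises and 10 largest falls of each contrast among called genes whose genotypes did not overlap, up to 4 called members of each list per contrast with the largest change (or up to 2 with the smallest p where none passed), and the 10 largest Wip1-/- changes that moved back. Genes whose symbol is only a clone or locus identifier were counted, and would have been named only where fewer than 5 others qualified (122, 126 and 173 of the called genes in the 3 contrasts). Where other detected probes of a named gene differed in sign or in passing the threshold, their values were to stand beside it. The text gives only a part of the genes that the rule names. Those given held their call without each array, except where the text says otherwise. A gene that the rule names among the rises in the arrays labelled Wip1-/- Atm+/- relative to Wip1-/- is not reported here. Genes outside the rule, named after their values were seen, are the endothelial genes Tek, Cdh5 and Eng and genes named as neighbours of others. So are the mitochondrially encoded genes among the closing observations.

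The same steps were tested on simulated data for Wip1-/- versus wild type with 10556 genes, a few of them given known fold changes. By limma 58 of 100 genes changed 1.5-fold were called, 50 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 12 false calls among 170. No list without changed genes was called (0), and a share set to 0.5 was recovered as 0.511. Genes were drawn independently, so false list calls from correlated members could not arise there. Without holding arrays out the share was recovered as 0.509, so the simulation does not show what the holding out gains. The alternatives tried were no background correction, normexp on the signals alone with an offset of 50, median scaling, cyclic loess, the authors' processed values, no filter on dim probes, detection at p under 0.01 on all 9 arrays, all detected probes in place of 1 per gene, only the genotypes compared, an intensity trend with robust moderation, array weights, the replicate number as a block, stricter thresholds, and leaving out each array in turn. A slide or chip alternative was not run, because none is given in the sources used here. Intervals of list medians are percentile intervals at 95% from 10000 bootstrap draws of the members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.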

Results

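Gene expression was measured in mouse spermatids, the haploid cells that mature into sperm after meiosis, from 3 genotypes. The wild type was compared with cells labelled Wip1-/-, for loss of the phosphatase encoded by Ppm1d, and with cells labelled Wip1-/- Atm+/-, for the further loss of 1 allele of Atm. Wip1 removes phosphate groups placed by the DNA damage kinase ATM and dampens that signal. The series title sets the question of whether Wip1 acts through ATM and BRCA1 on DNA methylation and heterochromatin. Each genotype was hybridized to 3 bead arrays, 9 in all. The median scanner intensity ran from 100.5 to 121.8 over the 9 arrays, and between 37.9% and 42.0% of 43582 probes were detected on each. After normalization 10556 genes were tested. Log2 levels correlated at 0.989 to 0.994 between arrays of 1 genotype and at 0.959 to 0.984 between genotypes, across genes, which are not independent replicates. The median SD over genes was 0.17 in wild type, 0.13 in Wip1-/- and 0.15 in the arrays labelled Wip1-/- Atm+/- (n = 3 each). The labels do not say whether the 3 arrays of a genotype came from separate animals. All p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

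The targeted genes were examined first. Ppm1d, read by the brightest of its probes (ILMN_3133522), had a log2 level of 9.35 ± 0.18 (SD, n = 3) in wild type and 8.70 ± 0.15 (SD, n = 3) in Wip1-/-. It fell by 0.66 (SE 0.13, limma adjusted p = 0.00511). In the arrays labelled Wip1-/- Atm+/- it stood at 9.46 ± 0.07 (SD, n = 3), 0.10 from wild type (limma adjusted p = 0.598) and 0.76 above Wip1-/- (limma adjusted p = 8.4e-04). This level does not show the loss of Ppm1d that the label gives, so these arrays are named by their label throughout. The same probe was still detected on all 3 Wip1-/- arrays, so it does not show an absence of the transcript there. A probe outside the deleted part of a gene checks nothing, and where the probes lie relative to the deletion is not given in the sources used here. Of the other Ppm1d probes, ILMN_1226504 was detected only on the 3 Wip1-/- arrays, where it stood at 6.02 ± 0.18 (SD, n = 3), so it was higher there than in the genotypes without detection. ILMN_1237129 was detected on 2 wild type arrays, on 3 Wip1-/- arrays and on 0 of the arrays labelled Wip1-/- Atm+/-, and passed the threshold in no comparison. Atm, read by ILMN_2492491, stood at 7.09 ± 0.12 in wild type, 7.89 ± 0.03 in Wip1-/- and 6.37 ± 0.07 in the arrays labelled Wip1-/- Atm+/- (SD, n = 3 each). It rose by 0.81 in Wip1-/- (limma adjusted p = 6.9e-04) and fell by 0.71 in the arrays labelled Wip1-/- Atm+/- against wild type (limma adjusted p = 4.3e-04). Another Atm probe, ILMN_1258206, was higher than wild type in Wip1-/- and in the arrays labelled Wip1-/- Atm+/-, by 0.63 and 1.03, so the Atm probes gave opposite directions for the arrays labelled Wip1-/- Atm+/-. ILMN_2783896 changed by -0.09 and 0.40 without passing the threshold.

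**Figure D1:**
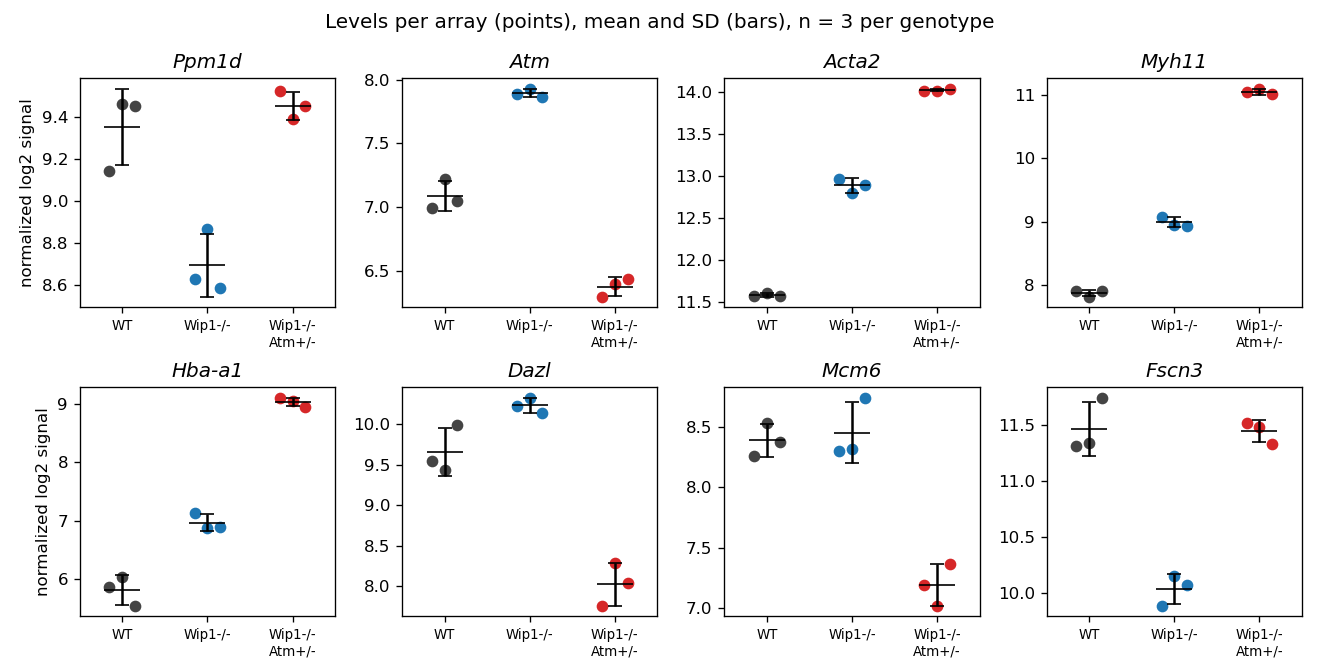
Normalized log2 signal (vertical axes, not starting at 0) of 8 genes on each array, grouped by the genotype label, with points for arrays and bars for the mean and SD of 3 arrays. Ppm1d was lower in Wip1-/- (8.70) than in wild type (9.35) and in the arrays labelled Wip1-/- Atm+/- (9.46), while Acta2 rose from 11.59 in wild type to 12.89 and 14.02.

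Between Wip1-/- and wild type, the 10 largest rises included genes expressed in vessel walls and connective tissue, Cldn5, Esam, Aoc3 and Ogn among them. Cldn5, a tight junction protein of endothelium, rose by 2.14 on the log2 scale (SE 0.17, limma adjusted p = 6.0e-05, n = 3 against 3). Esam, an endothelial adhesion molecule, rose at least 2.40-fold and Ly6c1, a surface protein of endothelial and myeloid cells, at least 3.07-fold, both undetected in wild type. Such bounds set the mean of the brighter genotype against the dimmer one's mean of, on each array, the higher of the lowest signal among detected probes and the probe's own signal. Aoc3, an amine oxidase of vascular smooth muscle, rose by 1.72 and Ogn, a small leucine-rich proteoglycan, by 1.70. The largest rise was that of Vars2, a mitochondrial valyl-tRNA synthetase, at 2.18 (SE 0.15, limma adjusted p = 3.4e-05). Clec2d, a ligand of a natural killer cell receptor, rose at least 2.56-fold. Osr2, a zinc finger transcription factor, rose by 1.67, Rdm1, which carries an RNA recognition motif, by 1.67 and Ifitm3, an interferon-induced membrane protein, by 1.63. The deepest fall was that of Tent5b, a poly(A) polymerase, which fell by 2.77 (SE 0.14, limma adjusted p = 3.7e-06). Sh3bgrl3 fell by 1.90, Mrto4, a ribosome assembly factor, by 1.79, and Gpn2, a GTPase, by 1.78. Ctcfl, the testis paralogue of the insulator protein CTCF, fell by 1.51, Gsdmd, which forms membrane pores in pyroptosis, by 1.64, and the transcription factor genes Onecut3 and Lhx1 by 1.65 and 1.45. Npcd fell by 1.52 and Mpo, the myeloperoxidase gene, by 1.46.

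Markers of peritubular, vascular and stromal cells rose as a group in Wip1-/-. Of 19 members tested, 14 rose and 1 fell, and the counts adjusted over the list alone were also 14 and 1. The median change was 0.79 (limma camera adjusted p = 3.15e-08). Igfbp7, an insulin-like growth factor binding protein of vessel walls, rose by 1.54 (SE 0.13), Pdgfra, a receptor of fibroblastic cells, by 1.49 (SE 0.12), Acta2, smooth muscle actin, by 1.30 (SE 0.10) and Col4a1, a basement membrane collagen, by 1.25 (SE 0.12). Genes of the elongating spermatid and flagellum shifted down by a median of -0.14 over 26 members (limma camera adjusted p = 0.0126). Of these, 0 rose and 4 fell, with the same counts adjusted over the list alone. This call gave an adjusted p = 0.223 with an estimated correlation, an adjusted p = 0.057 without wild type replicate 3 and an adjusted p = 0.058 with cyclic loess. Fscn3, a testis-specific actin bundling protein, fell by 1.42 (SE 0.14), and Spata3 by 0.47 (SE 0.10). Spata18 fell by 0.54 and Hk1, a hexokinase gene with a spermatogenic form, by 0.52, calls that ended without Wip1-/- replicate 1 (adjusted p = 0.057 and 0.054) and without Wip1-/- replicate 3 (0.053 and 0.052). Sex-chromosome genes of spermatids also shifted down, by a median of -0.32 over 17 members (limma camera adjusted p = 0.0309). In this list 1 member rose and 3 fell, or 2 and 6 adjusted over the list alone, and the call gave an adjusted p = 0.511 with an estimated correlation. It ended without wild type replicate 3 (0.195), without Wip1-/- replicate 1 (0.076) and without Wip1-/- replicate 3 (0.058), with genes detected on all 9 arrays (0.0999), with only the genotypes compared (0.0713) and with fry (0.0975). Cypt2 and Cypt3, cysteine-rich genes of the perinuclear theca, fell by 0.92 (SE 0.18) and 0.70 (SE 0.12).

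Genes of the exchange of histones for protamines went both ways. Of 22 members, 1 rose and 6 fell, or 3 and 7 adjusted over the list alone, and the list was not called (limma camera adjusted p = 0.269, and 0.0485 with median scaling). In the arrays labelled Wip1-/- Atm+/- 3 rose and 3 fell against wild type and 6 rose and 3 fell relative to Wip1-/-, the same adjusted over the list alone (limma camera adjusted p = 0.915 and 0.635). H1f7, a linker histone of spermatids, fell by 0.66 (SE 0.10), Camk4, a kinase of elongating spermatids, by 0.63 (SE 0.11), Tnp2, a transition protein, by 0.49 (SE 0.11) and Hils1, another spermatid linker histone, by 0.47 (SE 0.10). Among DNA damage and homologous recombination genes 5 of 19 rose and 0 fell, also 5 and 0 adjusted over the list alone (limma camera adjusted p = 0.109, not called). Among DNA methylation and heterochromatin genes 3 of 17 rose and 0 fell, or 4 and 0 adjusted over the list alone (limma camera adjusted p = 0.292, not called), with Kmt5c, a histone H4 methyltransferase, up by 0.56 (SE 0.12). Among p53 targets 2 of 20 rose and 1 fell, or 1 and 1 adjusted over the list alone (limma camera adjusted p = 0.604, not called). Ddb2, a damage recognition factor, rose by 0.57 (SE 0.13), with 0.37 to 0.51 at its 3 other probes. Imprinted genes counted 6 rises and 0 falls among 14, or 7 and 0 adjusted over the list alone, without a call (limma camera adjusted p = 0.109), and Ndn, the necdin gene, rose by 0.94 (SE 0.12).

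In total 2091 genes, 19.8% of those tested, differed between Wip1-/- and wild type by limma at an adjusted p under 0.05. Of these 1209 were higher and 882 lower in Wip1-/-, and 115 and 81 changed by more than 2-fold. The median absolute log2 change among them was 0.60. The genotypes did not overlap for 38.0% of genes, where chance gives 10%. Without Wip1-/- replicate 1 the count was 1209 and without Wip1-/- replicate 3 it was 1275. With median scaling in place of quantile normalization the median of all genes was 0.11 in Wip1-/- against wild type, -0.15 in the arrays labelled Wip1-/- Atm+/- against wild type and -0.21 in these arrays against Wip1-/-, where quantile normalization gave 0.04, -0.03 and -0.02. With median scaling the share of called genes that were higher was 71.7%, 35.0% and 25.8% in these comparisons, against 57.8%, 52.7% and 48.1% with quantile normalization and 58.5%, 62.5% and 56.3% with cyclic loess.

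In the arrays labelled Wip1-/- Atm+/-, the 10 largest rises against wild type included Myh11, Ccn2, Ccn5, Ogn and Col4a5, genes of smooth muscle and extracellular matrix. Myh11, the smooth muscle myosin heavy chain, rose by 3.17 on the log2 scale (SE 0.10, limma adjusted p = 9.5e-09, n = 3 against 3). Ccn2 and Ccn5, secreted matricellular proteins, rose by 3.20 (SE 0.11) and 3.30 (SE 0.17), Ogn by 3.29, Osr2 by 3.20 and Col4a5, a basement membrane collagen, by 3.24 (SE 0.20). Hba-a1, an adult alpha globin, rose by 3.21 (SE 0.14), and ND4L, a mitochondrially encoded subunit of complex I, by 3.25 (SE 0.31). Adgrg7, an adhesion G protein-coupled receptor, rose at least 7.69-fold and Gal3st2, a sulfotransferase, at least 6.92-fold, both undetected in wild type. Among the falls, Cstdc3, of the cystatin family, was at least 21.5-fold lower, Abhd10, a mitochondrial thioesterase, at least 13.3-fold, Spint1, a serine protease inhibitor, at least 5.31-fold and Guca2b, encoding uroguanylin, at least 4.17-fold. Each of these 4 genes was undetected in the arrays labelled Wip1-/- Atm+/-. Haus1, a subunit of the spindle complex augmin, fell by 4.50 (SE 0.21), and Atg3, an enzyme of autophagy, fell by 2.95 (SE 0.25). Cd96, a lymphocyte receptor, fell by 2.59 (SE 0.18), Nnmt, nicotinamide N-methyltransferase, fell by 2.46 (SE 0.12) and Nkx6-1, a homeobox gene, fell by 2.43 (SE 0.14). Abhd10 and Cd96 are neighbouring genes. Kif23, a kinesin of cytokinesis, fell by 2.48 (SE 0.14), while its other probes gave -0.79 and 0.32.

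Markers of cells other than spermatids moved in several directions in the arrays labelled Wip1-/- Atm+/- against wild type. Of 19 peritubular, vascular and stromal markers 14 rose and 0 fell, also 14 and 0 adjusted over the list alone, with a median of 2.07 (limma camera adjusted p = 2.54e-12). Pdgfra rose by 3.08 (SE 0.12), Col4a1 by 2.80 (SE 0.12) and Des, the muscle intermediate filament desmin, by 2.57 (SE 0.22). Among the endothelial members of this list, Tek and Cdh5 were not called, while Eng was higher. Erythroid markers rose in 4 of 5 members, likewise adjusted over the list alone, with a median of 2.73 (limma camera adjusted p = 6.6e-04, and adjusted p = 0.0555 with an estimated correlation). Klf1, an erythroid transcription factor, rose by 2.92 (SE 0.13) and Hbb-bs, a beta globin, by 2.73 (SE 0.15). Sertoli cell markers counted 7 rises and 0 falls among 14, or 8 and 0 adjusted over the list alone, with a median of 0.55 (limma camera adjusted p = 0.00112, and adjusted p = 0.0555 with an estimated correlation). The largest of these was Vim, vimentin, at 2.02 (SE 0.15), which mesenchymal cells in general also express. Trf, transferrin, rose at least 1.62-fold, Wnt6 by 0.79 (SE 0.12) and Cst12, a cystatin, by 0.69 (SE 0.16). Spermatogonium markers fell in 8 of 13 members and rose in 0, also 8 and 0 adjusted over the list alone, with a median of -0.56 (limma camera adjusted p = 0.00447, and adjusted p = 0.0771 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, fell by 1.63 (SE 0.17), Rhox13 by 1.17 (SE 0.11), Uchl1, a ubiquitin hydrolase, by 1.02 (SE 0.14) and Kit, the stem cell factor receptor, by 0.82 (SE 0.15), with -0.38 at its other probe.

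Proliferation genes fell in the same comparison. Of 24 genes of the mitotic cell cycle 1 rose and 13 fell, or 1 and 15 adjusted over the list alone, with a median of -0.47 (limma camera adjusted p = 4.93e-05). Mcm2, of the replicative helicase, was at least 1.99-fold lower, Mcm6, of the same helicase, fell by 1.20 (SE 0.15) and Mad2l1, of the spindle checkpoint, by 1.37 (SE 0.14). Ccnd2, a cyclin of the G1 phase, went the other way and rose by 1.95 (SE 0.16). Genes of the X chromosome shifted up by a median of 0.12 over 341 members, with 88 higher and 32 lower, or 89 and 34 adjusted over the list alone (limma camera adjusted p = 0.0147). That call gave an adjusted p = 0.395 with an estimated correlation and an adjusted p = 0.071 without wild type replicate 1. The largest changes on the X chromosome were rises of matrix and cytoskeletal genes, Col4a5, Bgn, a matrix proteoglycan, at 2.39 (SE 0.10) and Flna, filamin A, at 2.33 (SE 0.20), and of Slc38a5, an amino acid transporter, at 3.10 (SE 0.11). In Wip1-/- against wild type 44 genes of the X chromosome were higher and 72 lower, or 50 and 77 adjusted over the list alone, with a median of -0.02 (0.06 with median scaling) and no call for the list (limma camera adjusted p = 0.0975). That list was called with no background correction (0.0469), with genes detected on all 9 arrays (2.4e-04) and without wild type replicate 1 (0.008). Imprinted genes shifted up by a median of 0.24 over 14 members, with 5 higher and 1 lower, or 7 and 1 adjusted over the list alone (limma camera adjusted p = 0.0363). The imprinted call gave an adjusted p = 0.169 with an estimated correlation, and it ended without wild type replicate 1 (0.073). Ndn rose by 2.73 (SE 0.12), Igf2, a fetal growth factor, by 2.09 (SE 0.13), Impact by 2.00 (SE 0.14) and Kcnq1ot1, an imprinted long non-coding RNA, by 0.79 (SE 0.16).

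DNA damage and homologous recombination genes counted 0 rises and 8 falls among 19, also 0 and 8 adjusted over the list alone, without a call for the list (limma camera adjusted p = 0.101). Ung, the uracil glycosylase, fell by 1.02 (SE 0.15), while the probes of Rpa2, of the single-strand binding complex, gave -1.07 and 0.55. Among DNA methylation and heterochromatin genes 0 rose and 4 of 17 fell, as adjusted over the list alone (limma camera adjusted p = 0.212, not called). Dnmt3b, a de novo DNA methyltransferase, fell by 0.90 (SE 0.15) and Setdb1, a histone H3 methyltransferase, by 0.47 (SE 0.11). By limma 3103 genes, 29.4% of those tested, differed between the arrays labelled Wip1-/- Atm+/- and wild type, 1634 higher and 1469 lower. Of these 628 rose and 178 fell by more than 2-fold. The genotypes did not overlap for 41.3% of genes, where chance gives 10%. In 464 of the called genes the probe was undetected in at least 1 of the 2 genotypes, so that their fold is at best bounded.

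**Figure D2:**
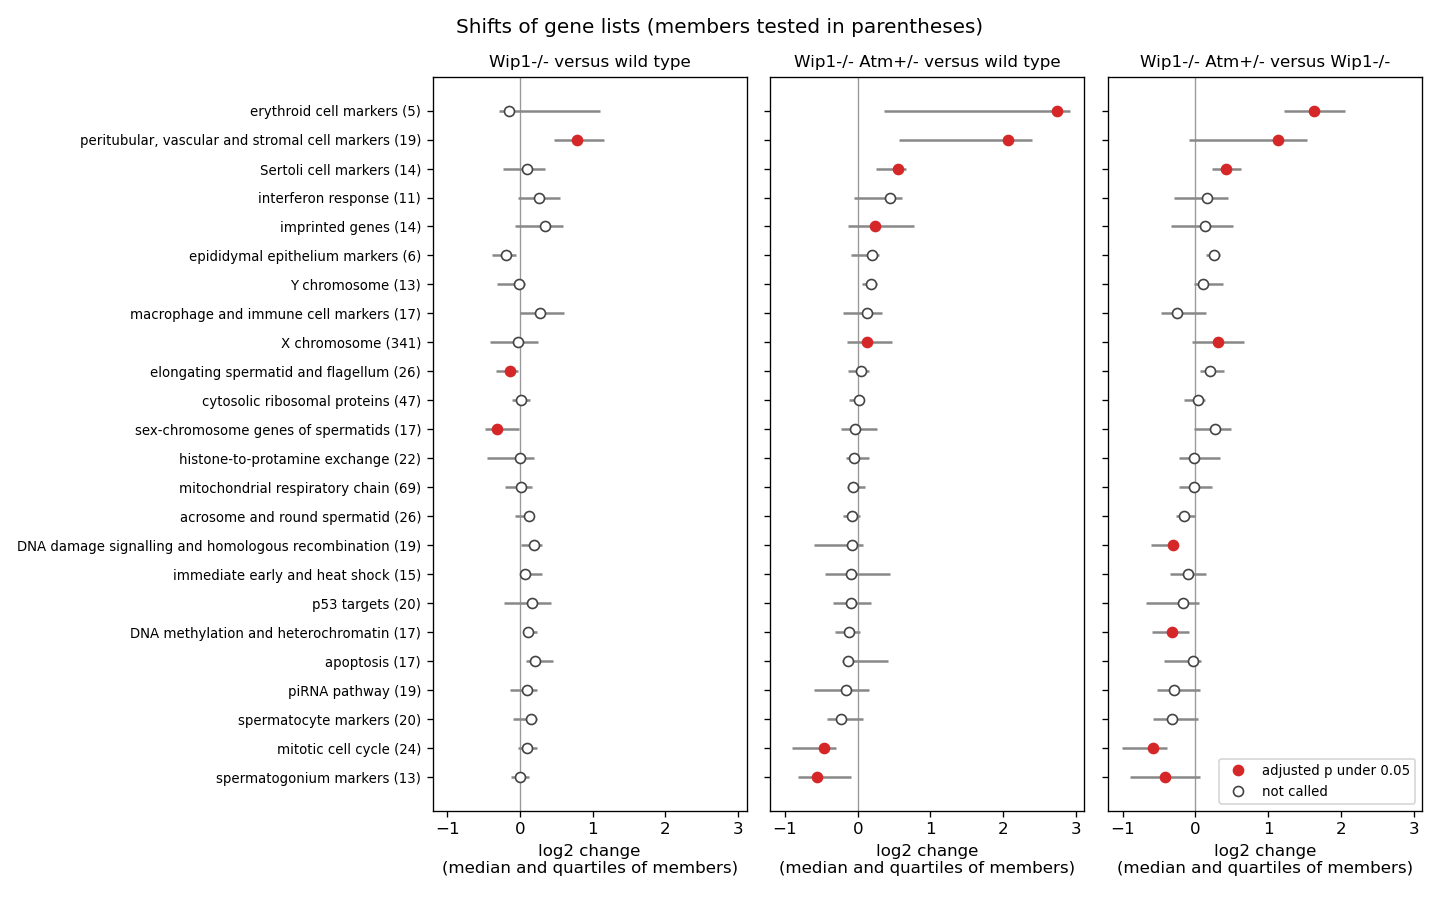
Median (points) and quartiles (lines) of the log2 change of the tested members of each of 24 gene lists, with the number of members in parentheses, for the 3 comparisons (horizontal axes). Filled points have a camera adjusted p under 0.05, and the peritubular, vascular and stromal markers have medians of 0.79, 2.07 and 1.13 from left to right.

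Relative to Wip1-/-, the arrays labelled Wip1-/- Atm+/- were lower in genes of the mitotic cell cycle and higher in most peritubular, vascular and stromal markers. Of the 24 mitotic genes 1 rose and 16 fell, or 1 and 17 adjusted over the list alone, with a median of -0.59 (limma camera adjusted p = 2.64e-06). Ccne2, a cyclin of S phase entry, fell by 1.70 (SE 0.23), Mad2l1 by 1.37 (SE 0.14) and Mcm6 by 1.26 (SE 0.15). Peritubular, vascular and stromal markers counted 13 rises and 3 falls among 19, the same adjusted over the list alone, with a median of 1.13 (limma camera adjusted p = 2.4e-05). Myh11 rose by 2.06 (SE 0.10), Col1a1, a fibrillar collagen, by 2.01 (SE 0.15) and Des by 1.83 (SE 0.22), n = 3 against 3. The endothelial members Tek and Cdh5 were among the 3 falls (-0.79 and -0.51), and Eng was not called (0.003). X chromosome genes shifted up by a median of 0.32 over 341 members, with 133 higher and 36 lower, or 143 and 37 adjusted over the list alone (limma camera adjusted p = 4.5e-06, and adjusted p = 0.167 with an estimated correlation). Tex13b, a germ cell gene of the X chromosome, went the other way and fell by 2.08 (SE 0.14), while Slc38a5 rose by 1.82 (SE 0.11).

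Genes of DNA damage signalling and homologous recombination fell in the arrays labelled Wip1-/- Atm+/- relative to Wip1-/-. Of 19 members 0 rose and 7 fell, also 0 and 7 adjusted over the list alone, with a median of -0.31 (limma camera adjusted p = 0.00112, and adjusted p = 0.0555 with an estimated correlation). The Atm probe ILMN_2492491 fell by 1.52 (SE 0.11), while the other Atm probes gave 0.40 and 0.49. Uimc1, of a BRCA1 complex at DNA breaks, fell at least 1.21-fold and Palb2, the partner of BRCA2, at least 1.33-fold. DNA methylation and heterochromatin genes shifted down by a median of -0.33 over 17 members, with 1 higher and 7 lower, or 1 and 9 adjusted over the list alone (limma camera adjusted p = 0.0309). The methylation call gave an adjusted p = 0.42 with an estimated correlation, and it ended without Wip1-/- replicate 3 (0.055), without Wip1-/- Atm+/- replicate 2 (0.057) and with genes detected on all 9 arrays (0.128). Dnmt3b fell by 1.01 (SE 0.15), Dnmt1, the maintenance DNA methyltransferase, by 1.01 (SE 0.22), Setdb1 by 0.89 (SE 0.11) and Kmt5c by 0.60 (SE 0.12). Spermatogonium markers moved with these lists, with 1 rise and 7 falls among 13, or 1 and 8 adjusted over the list alone, and a median of -0.42 (limma camera adjusted p = 0.0363). The spermatogonium call gave an adjusted p = 0.169 with an estimated correlation, and it ended without Wip1-/- replicate 2 (0.064), without Wip1-/- Atm+/- replicate 3 (0.057), with no background correction (0.0522), with normexp (0.0528) and with median scaling (0.104). Dazl fell by 2.21 (SE 0.17), while Lhx1 rose by 1.57 (SE 0.13). As mitotic genes also fell (median -0.59) and peritubular, vascular and stromal markers rose (median 1.13), changes within spermatids cannot be told apart here from changed cell proportions.

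Erythroid markers rose in 4 of 5 members relative to Wip1-/-, likewise adjusted over the list alone, with a median of 1.63 (limma camera adjusted p = 1.42e-04, and adjusted p = 0.0528 with an estimated correlation). Klf1 rose by 3.06 (SE 0.13), and Car2, a carbonic anhydrase, by 1.22 (SE 0.10). Sertoli cell markers counted 6 rises and 0 falls among 14, the same adjusted over the list alone, with a median of 0.42 (limma camera adjusted p = 0.00442, and adjusted p = 0.0771 with an estimated correlation), and Wnt6 rose by 0.96 (SE 0.12). Among the largest single rises were those of Adgrg7, at least 8.50-fold, Gal3st2, at least 7.65-fold, Tent5b by 3.43 (SE 0.14) and Cap1, an actin regulator, by 2.69 (SE 0.13). Serpina1b, an alpha-1-antitrypsin gene, rose by 2.65 (SE 0.20) and Kcnab2, a potassium channel subunit, by 2.32 (SE 0.15). Cstdc3, Abhd10, Guca2b, Spint1 and Sall3, a zinc finger gene, were at least 10.7-, 12.1-, 6.35-, 5.16- and 2.91-fold lower. Haus1 fell by 4.33 (SE 0.21), Atg3 by 3.19 (SE 0.25), Nkx6-1 by 2.66 (SE 0.14) and Sdad1 by 2.49 (SE 0.17), and Kif23 by 2.80 (SE 0.14), with -0.91 and 0.01 at its other probes. By limma 3667 genes, 34.7% of those tested, differed between Wip1-/- and the arrays labelled Wip1-/- Atm+/-, 1765 higher and 1902 lower in the latter. More than 2-fold changes numbered 521 up and 263 down, and the genotypes did not overlap for 49.3% of genes, where chance gives 10%.

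Lists called in part of the comparisons gave these values in the others. Genes of the elongating spermatid and flagellum had a median of 0.05 against wild type in the arrays labelled Wip1-/- Atm+/- (limma camera adjusted p = 0.974, and a median of -0.06 with median scaling), with 0 rises and 1 fall, as adjusted over the list alone. Relative to Wip1-/- their median was 0.19 (limma camera adjusted p = 0.0908), with 7 rises and 2 falls, as adjusted over the list alone. That list was called there with median scaling (3.7e-04), no filter on dim probes (0.0206), all detected probes (0.0154) and fry (0.00385) and without Wip1-/- replicate 2 (0.038). Sex-chromosome genes of spermatids had medians of -0.03 and 0.26 in the same comparisons (limma camera adjusted p = 0.941 and 0.173), with 2 rises and 1 fall and then 5 and 1, the same adjusted over the list alone, and the latter was called with all detected probes (0.0396). Imprinted genes had a median of 0.13 relative to Wip1-/- (limma camera adjusted p = 0.239, and a median of -0.08 with median scaling), with 5 rises and 2 falls, as adjusted over the list alone. In Wip1-/- against wild type the medians were 0.09 for the mitotic cell cycle, -0.01 for spermatogonium markers (0.14 with median scaling), 0.10 for Sertoli cell markers and -0.15 for erythroid markers (limma camera adjusted p = 0.242, 0.626, 0.842 and 0.933). These lists counted 4, 1, 2 and 2 rises and 0, 1, 1 and 1 falls, or 4, 1, 3 and 2 and 0, 1, 2 and 1 adjusted over the list alone. With all detected probes the mitotic and erythroid lists were called there (0.0340 and 0.0112). In the main test the camera direction of the erythroid list was up, with a mean of 0.19, although its median was -0.15.

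The other lists were not called in any of the 3 comparisons by the main test, given here in the order Wip1-/- against wild type, arrays labelled Wip1-/- Atm+/- against wild type, and the same arrays against Wip1-/-. With fry, which asks whether members move one way, some were called. In the last comparison these included piRNA genes (fry adjusted p = 7.3e-04) and p53 targets (0.0032). In the 2nd they included spermatocyte markers (0.0020) and interferon response genes (0.0063). Genes of the piRNA pathway, which silences transposons in germ cells, had medians of 0.10, -0.16 and -0.29 over 19 members (limma camera adjusted p = 0.626, 0.135 and 0.0640). Relative to Wip1-/- 1 rose and 8 fell, or 2 and 8 adjusted over the list alone, and Rnf17 and Mov10l1 fell by 1.53 (SE 0.13) and 1.13 (SE 0.14). Spermatocyte markers had medians of 0.15, -0.24 and -0.32 over 20 members (adjusted p = 0.666, 0.129 and 0.0908), with 2 rises and 7 falls relative to Wip1-/-, or 2 and 8 adjusted over the list alone. Tex101, a germ cell surface protein, fell by 1.80 (SE 0.18) there, and Syce2, of the synaptonemal complex, rose by 1.37 (SE 0.23). Acrosome and round spermatid genes had medians of 0.12, -0.08 and -0.16 over 26 members (adjusted p = 0.626, 0.368 and 0.183), with 1 rise and 5 falls relative to Wip1-/-, or 1 and 4 adjusted over the list alone. Their median in Wip1-/- against wild type was -0.01 with median scaling. Macrophage and immune markers had medians of 0.28, 0.13 and -0.26 over 17 members (adjusted p = 0.129, 0.626 and 0.389). In this order 5, 2 and 1 rose and 1, 2 and 5 fell, or 5, 2 and 2 and 1, 2 and 7 adjusted over the list alone. Relative to Wip1-/- C1qb, of complement, rose by 1.73 (SE 0.14), and Lyz2, lysozyme, fell by 1.40 (SE 0.14).

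Interferon response genes had medians of 0.26, 0.45 and 0.16 over 11 members (limma camera adjusted p = 0.380, 0.135 and 0.521), with 5 rises and 1 fall against wild type in the arrays labelled Wip1-/- Atm+/-, or 6 and 1 adjusted over the list alone. Gbp2, a guanylate-binding protein, was among them at least 1.29-fold higher. Immediate early and heat shock genes had medians of 0.06, -0.10 and -0.10 over 15 members (adjusted p = 0.515, 0.974 and 0.763). Klf6 rose by 1.41 (SE 0.12) and Egr1 fell by 0.98 (SE 0.13) in the arrays labelled Wip1-/- Atm+/- against wild type, where the list had 4 rises and 4 falls, as adjusted over the list alone. Apoptosis genes had medians of 0.20, -0.14 and -0.04 over 17 members (adjusted p = 0.203, 0.936 and 0.431), with 2 rises and 5 falls relative to Wip1-/-, or 3 and 7 adjusted over the list alone. The p53 targets had medians of 0.17, -0.10 and -0.17 over 20 members (adjusted p = 0.604, 0.317 and 0.165), with 2 rises and 8 falls relative to Wip1-/-, the same adjusted over the list alone, and Ddb2 fell there by 1.46 (SE 0.13). Cytosolic ribosomal protein genes, with medians of 0.02, 0.01 and 0.03 over 47 members (adjusted p = 0.974, 0.811 and 0.933), had 4 rises and 4 falls relative to Wip1-/-, or 3 and 4 adjusted over the list alone. With median scaling their medians were -0.08, -0.15 and -0.03. Genes of the mitochondrial respiratory chain encoded in the nucleus had medians of 0.02, -0.06 and -0.02 over 69 members (adjusted p = 0.519, 0.660 and 0.974), with 10 rises and 7 falls relative to Wip1-/-, or 2 and 5 adjusted over the list alone. With median scaling their median in Wip1-/- against wild type was -0.06 (adjusted p = 0.0182). The 13 Y chromosome genes tested had medians of -0.01, 0.18 and 0.10 (adjusted p = 0.359, 0.521 and 0.230), with 2 rises relative to Wip1-/-, the same adjusted over the list alone, among them H2al2c, a spermatid histone variant, at 1.41 (SE 0.14). Markers of the epididymal epithelium had medians of -0.19, 0.20 and 0.26 over 6 members (adjusted p = 0.323, 0.763 and 0.317), with 1 rise relative to Wip1-/-, also 1 adjusted over the list alone. Only 4 Leydig cell markers were tested, too few for the list test, and 2 of them rose against wild type in the arrays labelled Wip1-/- Atm+/-, as adjusted over the list alone. These were Aldh1a1, a retinal dehydrogenase, at 2.26 (SE 0.26) and Gstm1, a glutathione transferase, at 2.53 (SE 0.12), with -0.36 at its other probe. No probe could be assigned to the list of retroelement-derived sequences, so 0 members were tested. The list calls that held with an estimated correlation were those of the peritubular, vascular and stromal markers in all 3 comparisons (adjusted p = 0.0199, 0.0124 and 0.0317) and of the mitotic genes in both comparisons that involve the arrays labelled Wip1-/- Atm+/- (0.0317 and 0.0255).

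The label Atm+/- raises the question of which Wip1-/- changes persist. Of the genes with the largest Wip1-/- changes, several moved back towards or past the wild type level in the arrays labelled Wip1-/- Atm+/-. Cldn5 fell back by a log2 change of -1.89 (SE 0.17), Vars2 by -1.81 (SE 0.15), Ly6c1 by -1.77 (SE 0.17), Esam by at least 2.41-fold and Rdm1 by -1.06 (SE 0.14), relative to Wip1-/-. Tent5b, Sh3bgrl3, Mrto4 and Gpn2, all lower in Wip1-/-, came back up by 3.43, 2.63, 2.25 and 2.22. Tent5b, Mrto4 and Gpn2 lie on the same chromosome, each next to another tested gene that changed more than 2-fold. Map3k6, beside Tent5b, changed by -1.03 in Wip1-/- against wild type and by 1.70 in the arrays labelled Wip1-/- Atm+/- against Wip1-/-. In the same comparisons Trnp1, on the other side of Tent5b, changed by -0.22 and 1.97, and Cd164l2, beside Map3k6, by -1.07 and 0.71. Akr7a5 and Ubr4, on either side of Mrto4, changed by -0.46 and 1.02 and by -0.37 and 1.09. Pigv, beside Gpn2, went the other way (0.26 and -1.07). Between Gpn2 and Mrto4 in gene order, Kif17 changed by -1.03 and 1.78 and Camk2n1 by -0.75 and 1.35. Alpl and Ece1, also between them, did not fall in Wip1-/- (1.11 and 0.77). Whether the falls of Tent5b, Mrto4 and Gpn2 are separate changes was not tested. Tent5b, Sh3bgrl3 and Mrto4 then stood above wild type by 0.65, 0.73 and 0.47, and Rdm1 still stood above it by 0.61 (limma adjusted p of 0.0119 or less). Clec2d moved back by only -0.40 (SE 0.11, limma adjusted p = 0.0141), which ended without Wip1-/- replicate 3 (0.062) and with an intensity trend and robust moderation (0.0738). By contrast Igfbp7, Pdgfra, Acta2, Col4a1, Aoc3, Ogn, Osr2 and Ifitm3 were above Wip1-/- in the arrays labelled Wip1-/- Atm+/-. The Ppm1d probes disagreed and could not be placed against the deletion, so they settle the genotype of neither mutant. No direction drawn here is therefore assigned to the genotypes themselves.

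In number, 926 of the 2091 genes changed in Wip1-/- (44.3%) moved back past the threshold in the arrays labelled Wip1-/- Atm+/- relative to Wip1-/-. Of these 374 were higher in Wip1-/- and then lower, where independent lists of the same sizes would share 218, and 552 were lower and then higher, where independent lists would share 147. Simulated arrays equal to Wip1-/- gave a mean of 0.03 such genes and at most 1, which is chance with no effect between these groups and does not measure how far shared arrays raise the overlap where both comparisons hold effects. Against wild type 758 of the 926 genes were not called, 155 were called in the opposite direction and 13 in the original one. A further 375 genes moved further in the same direction, and 790 had no call relative to Wip1-/-. Without Wip1-/- replicate 1 the number that moved back was 533 and without Wip1-/- replicate 3 it was 538. In both Wip1-/- and the arrays labelled Wip1-/- Atm+/- 667 genes were higher than wild type (187 for independent lists) and 192 lower (123 for independent lists), with 0 in simulations with no effect in either. The log2 changes of Wip1-/- and of the arrays labelled Wip1-/- Atm+/- against wild type correlated at 0.436 across genes, where arrays without effects gave 0.501, and their covariance was 0.0999 against 0.0128 simulated, a difference of 0.0871. The change of Wip1-/- against wild type correlated with that of the arrays labelled Wip1-/- Atm+/- against Wip1-/- at -0.210, where simulated arrays equal to Wip1-/-, with the Wip1-/- shift kept, gave -0.192, and the covariance was -0.0443 against -0.0126 simulated, a difference of -0.0317. Part of these overlaps may come from the shared arrays.

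Measured on arrays not used to choose the genes, the arrays labelled Wip1-/- Atm+/- held a mean share of 0.837 of the Wip1-/- shift (0.738 to 0.900 over 9 choices of held-out arrays, each with 856 to 1400 genes). Over the alternatives it ran from 0.556 with genes detected on all 9 arrays to 0.979 without wild type replicate 1. The share differed by direction, a division made after the values were seen. For genes higher in Wip1-/- it was 1.42 (1.27 to 1.53) and for genes lower in Wip1-/- 0.0389 (-0.00593 to 0.0814), where 1 means the Wip1-/- level and 0 the wild type level. With median scaling these shares were 0.884 (0.786 to 0.963) and 0.230 (0.176 to 0.307). By a moderated F test of limma 4517 of 10556 genes differed among the 3 genotypes.

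**Figure D3:**
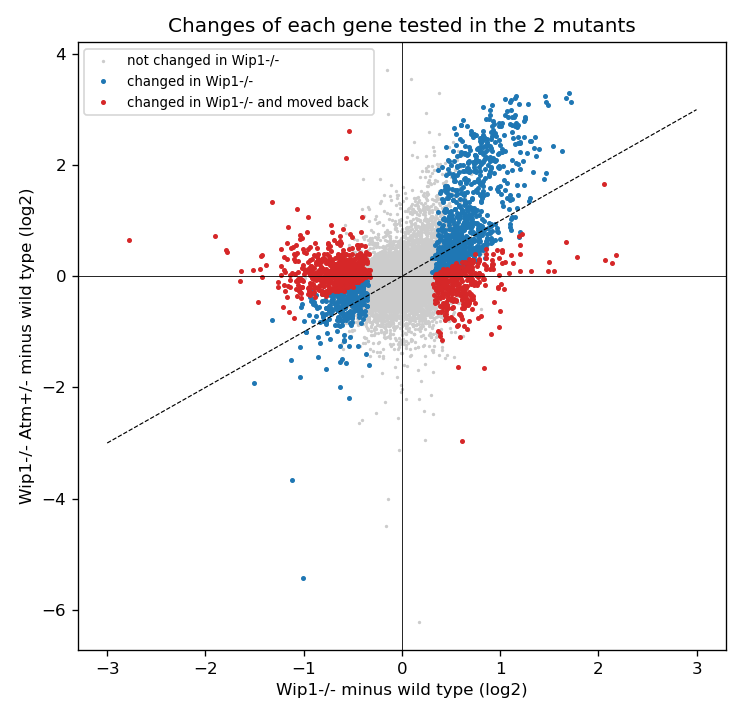
Log2 change of each of 10556 tested genes in Wip1-/- (horizontal axis) and in the arrays labelled Wip1-/- Atm+/- (vertical axis), both against wild type, with a dashed line of equal change. Red points are the 926 genes that changed in Wip1-/- and moved back, blue points the remaining genes changed in Wip1-/-, and many of the 1209 genes higher in Wip1-/- lie above the dashed line.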

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

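All tests in this part were chosen after the blank scanner cells were seen. A signal stood in data that the comparisons did not use, namely 1697 probes that lack complete scanner values but have processed intensities in the authors' table. On those values 161 of these probes passed the threshold between Wip1-/- and wild type, 297 between the arrays labelled Wip1-/- Atm+/- and wild type, and 316 between these arrays and Wip1-/-. These are 9.49%, 17.5% and 18.6% of the 1697 probes, with 95, 149 and 137 of them higher. Without detection p-values these probes could not be held to the same detection filter, so the shares are not comparable with those of the tested genes. No explanation of the blank cells was tested.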

How the results depend on the processing

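The tests chosen only after the result was seen are the block of array pairs that resembled each other in undetected probes and the split of the retained share by direction. No called named gene or called list changed direction under any alternative run, while medians of some lists without a call did, such as the cytosolic ribosomal proteins with median scaling, and so did Ppm1d in the arrays labelled Wip1-/- Atm+/- against wild type. For single named genes 3733 values kept their side of the threshold under the alternatives other than leaving out an array, 124 lost it and 15 gained it, and with 1 array left out 2735 kept it, 258 lost it and 4 gained it. For lists the numbers were 926, 23 and 50, and with 1 array left out 635, 10 and 3. The share of the Wip1-/- shift retained (0.837) was 0.606 with no background correction, 0.649 with normexp, 0.712 with median scaling, 0.676 on the authors' processed values, 0.556 with genes detected on all 9 arrays, 0.733 with all detected probes, 0.714 with an intensity trend and robust moderation, and 0.724 with all arrays used for both the choice and the measurement. The cause was not tested. All detected probes gave 3324, 5299 and 6336 changed features for the 3 comparisons, 7800 by the F test and 1522 moved back, since more features were tested. A change of at least 1.5-fold left 1124, 1943 and 2207 genes and an adjusted p under 0.01 left 901, 1917 and 2315, as stricter thresholds must. List calls numbered 18, against 30 with no filter on dim probes, 5 with an estimated correlation and 40 with fry, which tests a different question. The cause of the first was not tested. With 1 array left out, the counts ran from 1209 to 2052, 2494 to 2940 and 2890 to 3780, the F test from 3708 to 4524, the genes moved back from 533 to 858, the share from 0.825 to 0.979 and the list calls from 16 to 19. The replicate numbers did not pair the arrays, since correlations of same-numbered deviations ran from -0.298 to 0.272, and 3 of the 9 arrays correlated best with their own number. With the replicate number as a block the counts were 1842, 2896 and 3493, with 804 moved back, a share of 0.917 and 16 list calls. The imprinted call against wild type and the spermatogonium call relative to Wip1-/-, both for the arrays labelled Wip1-/- Atm+/-, had an adjusted p = 0.0516 with that block. A random block for the array pairs most alike in undetected probes gave 3046, 3351 and 4461. By signal over background, 206, 464 and 294 of the called genes were undetected in at least 1 of the 2 genotypes compared, and their fold is at best bounded. No slide alternative was run, because no slide is given in the sources used here.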

Other observations

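Chosen only after the result was seen were the genes named in this part, the tests by chromosome, of mitochondrially encoded genes, of linked sequence, of neighbours of the largest changes, of the label exchange by the level of Ppm1d and of the probe's place, and the peritubular minus macrophage difference. Some endothelial genes rose in Wip1-/- without a call against wild type in the arrays labelled Wip1-/- Atm+/-. Against wild type Cldn5 rose by 2.14 in Wip1-/-, and Tek, a receptor of endothelial cells, and Cdh5, the endothelial cadherin, both undetected in wild type, rose at least 1.49-fold and at least 1.20-fold. In the arrays labelled Wip1-/- Atm+/- against Wip1-/- the changes were -1.89, -0.79 and -0.51, all past the threshold by limma. Eng, endoglin, also undetected in wild type, was at least 1.49-fold higher in Wip1-/- and in these arrays, and did not move back (0.003 against Wip1-/-). As these genes were chosen for their values, no statement on endothelial genes as a group follows. Of 8 mitochondrially encoded genes tested, 3, 7 and 7 were higher in the 3 comparisons, with medians of 0.66, 1.66 and 1.15, and ND5 was the exception in each comparison of the arrays labelled Wip1-/- Atm+/- (-0.06 and 0.33). By chromosome, changes of more than 2-fold were more frequent on the X chromosome in these arrays against wild type (51 of 341 genes, where 7.37% changed elsewhere, Fisher adjusted p = 7.55e-05) and against Wip1-/- (52 of 341, where 7.15% did elsewhere, adjusted p = 1.66e-05), but not past the threshold in Wip1-/- against wild type (14 of 341, adjusted p = 0.0528). Chromosome 14 held more against wild type in the arrays labelled Wip1-/- Atm+/- (11.7% against 7.46%, adjusted p = 0.0466) and chromosome 19 fewer against Wip1-/- (3.65% against 7.54%, adjusted p = 0.0437). For the mitochondrially encoded genes the Fisher adjusted p was 0.00459, 7.4e-06 and 0.00177 in the 3 comparisons, and no other chromosome passed. These Fisher tests count genes as independent, although all genes were read on the same arrays, so their p-values may be too small. With an estimated correlation the X chromosome list gave a limma camera adjusted p = 0.395 and 0.167 in the arrays labelled Wip1-/- Atm+/- against wild type and Wip1-/-.

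Markers of peritubular, vascular and stromal cells stood higher in the arrays labelled Wip1-/- Atm+/- than in wild type, with a median of 2.07 (bootstrap 95% interval 0.72 to 2.35). The peritubular median exceeded that of macrophages by 1.94 (interval 0.557 to 2.29, drawn over list members and not arrays). This cannot decide on a larger share of all somatic cells. The offset shrinks changes of dim probes, so the lists need not rise alike. The planned rule, an interval wholly below 0 in at least 1 somatic list, was not met and left this open. By the planned rule the Sertoli median, whose interval began at 0.241, went against a change in peritubular and stromal cells alone. It cannot decide this, because that interval was also drawn over list members and not arrays, and Vim in that list is not specific. With an estimated correlation the Sertoli list was not called (limma camera adjusted p = 0.0555). Normalization is argued against, since the lowest peritubular median over 5 other corrections was 1.39. A change in cell proportions, or in expression within cells, may remain, which the genotype labels cannot separate.

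In 176 pairs, genes that changed more than 2-fold in any of the 3 comparisons were neighbours along chromosomes (gene order of GRCm38.p6). Permuted places gave a mean of 120 and at most 157, which argues against chance placement. With 50 genes on each side of Ppm1d and Atm left out, the pairs numbered 171 against at most 149. The genes left out thus do not account for the excess. As linked sequence beyond them was not tested, this cannot decide on linked sequence. Within single comparisons the pairs numbered 101 (at most 88 permuted) and 105 (at most 81) for the arrays labelled Wip1-/- Atm+/- against wild type and against Wip1-/-. In Wip1-/- against wild type they numbered 7, at the upper end of the central 95% of permutations (0 to 7). Of the 45 genes with the largest changes, 15 had such a neighbour, among them Tent5b, Mrto4, Gpn2, Atg3, Abhd10, Cd96 and Adgrg7, or 33.3% against 28.8% of all genes changed more than 2-fold. Abhd10 and Cd96 lie next to each other and both fell in the arrays labelled Wip1-/- Atm+/- against wild type. Adgrg7 and its neighbour Tmem45a both rose there. Cd200, beside Atg3, changed by 0.05, while Gm609, next after Cd200, changed by -2.63. Atg3, Abhd10, Cd96 and Adgrg7 lie on the same chromosome, and whether their changes are separate was not tested. Sequence variants under single probes cannot be told apart from changes of expression, as a second probe changed under 0.5 times as much in 46.2% of 91 genes with a changed neighbour and in 47.7% of 258 without. The permutation treated all genes alike, although some pairs belong to the same gene family, such as Col4a1 with Col4a2 and Hbb-bt with Hbb-bs. How far such pairs account for the excess was not tested. Strain differences may stay open, since the genetic background is not given in the sources used here, and no biological explanation was tested.

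At ILMN_3133522 Ppm1d was not lower in the arrays labelled Wip1-/- Atm+/- than in wild type, while ILMN_1237129 was detected on 0 of these arrays. An exchange of their labels with wild type would not account for this, since at that probe the arrays labelled wild type also exceeded Wip1-/-, by 0.66, but as its place is unknown it excludes no exchange as such, and ILMN_1226504 was detected only in Wip1-/-. The planned test, a retained share of 0.837, was void, because an exchange would also change the comparison that chose the genes. A probe outside the deleted part cannot be told apart from other causes by the difference of 0.10, as no probe could be placed against the deletion. A wrong genotype in these arrays may also remain, and no biological explanation was tested.

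For each comparison of 3 against 3 arrays the 10 possible splits are too few for a share under 0.05. The real splits gave 2091, 3103 and 3667 genes, and the highest other split gave 0 in each, so that 1 split of the 10 reached the real count. Among 100 splits of the 9 arrays into 3 groups, only the real one reached its 4517 genes (1 of 100), and the highest other gave 1861. This argues against a random assignment of these 9 arrays for that count. Since the labels do not say whether arrays of a genotype came from separate animals, the splits cannot exclude differences between animals or preparations.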
